A study of Mus musculus with 8 samples.

How the data were processed

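Colon cancer organoids of mouse, with Apc and Trp53 lost and Kras activated, were treated for 48 h with 10 µM norepinephrine or vehicle, in 4 replicates each. RNA was selected by its poly-A tail, made into Illumina TruSeq libraries and sequenced in paired ends on a NovaSeq, per the labels' protocols. The protocols do not say whether the libraries kept strand, so reads of overlapping antisense genes cannot be told apart. Base calls were converted with bcl2fastq 2.19 and transcripts quantified with kallisto 0.44.0 against GRCm38.p6, per the submitters' processing notes. The authors deposited 1 table of estimated counts per gene, which kallisto makes by sharing reads among the transcripts they fit. Near-identical gene copies therefore split reads by a model, and values of paralogs and of genes with many pseudogenes are less certain. All deposited values were whole numbers, so rounding changed none. The table holds 36144 genes by symbol, of which 25172 had a count in any library. Of the symbols, 99.4% matched GENCODE M21, from which positions, transcript lengths and GC content were taken. No column belonged to another series, and no library was left out.

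Totals ran from 35997701 to 47340204 counts, so that 3 counts, the number that a count of 0 allows, correspond to 0.0634 to 0.0833 CPM in vehicle and 0.064 to 0.0714 CPM in norepinephrine libraries. For a gene at 0 in the whole vehicle group, a lower bound of the fold was computed from 3 counts over the group. For a gene with 1 to 3 counts there, the ratio was given with an exact 95% counting interval. Other folds are the fitted values of the model.

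Low genes were removed with edgeR's filterByExpr, which left 15877 genes, 95.4% of them protein coding. The filter keeps a gene expressed in either group, so a gene silent in vehicle was tested only if it was expressed with norepinephrine. Counts were scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, norepinephrine against vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and principal components were computed on log2 CPM with a prior count of 2. The comparison, the test, the gene lists and the rule for naming genes were fixed before the data were examined.

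Gene lists were tested with camera from limma 3.58.1, with a preset correlation between genes of 0.01, and again with a correlation estimated for each list. Of 55 lists, the 54 with at least 5 tested members were tested and adjusted together. Camera compares a list with the other genes, and its direction can differ from the sign of the list's median. Members were also adjusted over the list alone. Of the listed genes, 12 were not in the table.

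Genes were named by a rule. It took the 8 largest increases and the 8 largest decreases among called genes with a mean log2 CPM of at least 1, a proper symbol and no overlap between groups. It took the 5 smallest p-values in each direction, up to 4 members with the smallest p from each called list and up to 2 from any other. It also held Apc, Kras, Trp53, the 9 adrenergic receptor genes, Ngf, Lgr5, Mki67, Krt20, Muc2 and Chga. The rule gave 193 genes, and the report gives the main ones. Members named because few of their list went a given way or were not called, Col1a2 and Gm2436 were chosen after their values were seen.

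The alternatives tried were DESeq2 size factors, library totals and upper quartile scaling in place of TMM; no filter and a filter of 50 counts in 4 libraries; the DESeq2 1.42.0 Wald test and limma-voom; the replicate number as a block; a test against a fold of 1.2; removal of mitochondrial genes and the 20 most abundant genes; and each library left out in turn. For lists, camera with an estimated correlation, camera on ranks and fry were tried. Chosen after seeing the data were a test against a fold of 2, removal of each library's loess trend (span 0.5) with transcript length or with GC content, thinning to the smallest total, the upper quartile and composition settings for lists, and 10000 random lists matched on mean expression for each list and for gene families picked from the results.

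The method was tested on simulated counts with the means and sizes of these libraries, for norepinephrine against vehicle. Of 50 genes at each fold among 15564, it called 34% at 1.1-fold, 74% at 1.25-fold, 80% at 1.5-fold and 100% at 2-fold. It made 12 false calls among 15339 unchanged genes and called 0 unmoved lists with camera. The unmoved lists were random genes, and each gene was simulated independently. The simulation therefore does not test list calls where the genes of a list are correlated. Few genes were moved in the simulation, so the TMM assumption that most genes do not change held there. In the data 90.3% of tested genes were called, so these rates may not carry over to them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.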

Results

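Transcript levels were measured by RNA sequencing in mouse colon cancer organoids, which are clusters of tumour epithelial cells grown in a basement membrane gel. The organoids lacked the tumour suppressors Apc and Trp53 and carried an activated Kras allele. They were treated for 48 h in low serum medium with 10 µM norepinephrine, the transmitter of sympathetic nerves, or with vehicle. Each group had 4 replicates, and the design text calls them independent. The 4 vehicle libraries held 45917236, 46344015, 47340204 and 35997701 estimated counts, and the 4 norepinephrine libraries held 46302140, 46888085, 42886964 and 41988144. Vehicle replicate 4 had the smallest total.

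The question was which genes norepinephrine raises or lowers in these tumour cells. The groups differed throughout the transcriptome: of 15877 tested genes, 7483 were higher and 6859 lower with norepinephrine (edgeR quasi-likelihood test, adjusted p under 0.05). Most listed genes of lipid synthesis, of extracellular matrix and its adhesion and of nerve-type signalling rose. Genes silent in vehicle were tested only if expressed with norepinephrine, so the rise of such genes was set in advance. Most listed genes of DNA replication, mitosis and the amino acid stress response fell. Ribosomal and antigen presentation lists moved too, lower and higher, but their calls ended with an estimated correlation. Large changes were mostly increases, with 2159 genes past 8-fold higher and 27 past 8-fold lower. Past 2-fold, 4904 genes were higher and 1911 lower. The 4 values of one group did not overlap the 4 of the other for 87.2% of tested genes, against 2.86% by chance. The first principal component separated the groups and held 95.3% of the variance, and the second held 1.14%. The biological coefficient of variation within groups was 2.75%. Nothing beyond the design text describes separate cultures, so the p-values measure the spread between these samples, which may be technical.

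Changes were sorted by expression level. Among genes with a mean log2 CPM (counts scaled to a common library total) above 8, 490 fell and 143 rose, with a median log2 fold change of -0.66. Between 0 and 2, 1424 rose and 250 fell, with a median of 1.62. In 578 genes the mean went from under 0.1 CPM in vehicle to 1 CPM or more, and only Gm2436 went the other way, with 186 against 2 counts and single vehicle libraries from 0 to 99. Norepinephrine libraries had more genes above 0, at 21092 to 21302 against 18815 to 19403 in vehicle. Fold changes are relative to the TMM scaling, which assumes that most genes do not change. Scaling by library totals instead would raise every log2 fold change by a median of 0.25, and the number of genes past 2-fold lower would be 1008.

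**Figure D1:**
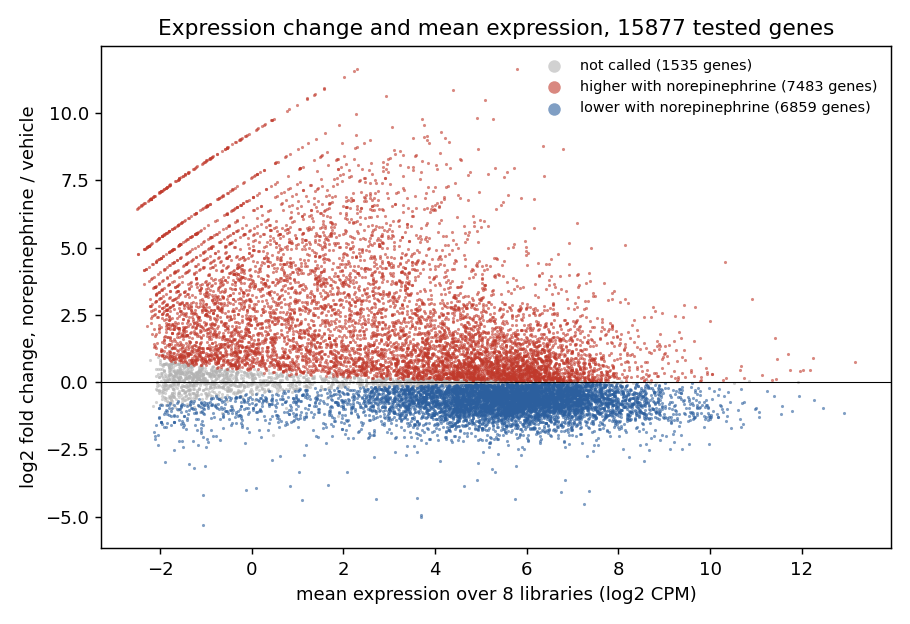
Log2 fold change (norepinephrine over vehicle, vertical axis) against mean expression over the 8 libraries (log2 CPM, horizontal axis). Each point is 1 of 15877 tested genes; 7483 were called higher (red), 6859 lower (blue) and 1535 not called (grey), and the slanted lines at the upper left are genes with 0 or few vehicle counts, whose fitted fold changes depend on the prior count.

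The largest increases were in genes nearly silent in vehicle. Col5a3, a fibrillar collagen chain, went from 0.0309 ± 0.022 CPM to 106 ± 2.6 CPM (SD, n = 4). Wnt3, a WNT ligand, had 0 counts in the vehicle group and 1742 with norepinephrine, which is at least 482-fold higher against a floor of 3 counts over the group. Rspo1, an enhancer of WNT signalling, was at least 394-fold higher by the same floor. The GABA transporter gene Slc6a13 was at least 460-fold higher, Cys1 at least 293-fold, Coch at least 289-fold and the translation factor gene Eef1a2 at least 255-fold. Adgrb2 had 3 vehicle counts, all in vehicle replicate 3 and 0 without it, and its ratio was 2135 with a 95% counting interval of 730 to 10350. These intervals and floors cover counting error only.

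Among the largest decreases were genes of 1-carbon and amino acid metabolism. Aldh1l2, a mitochondrial folate enzyme, fell from 295 ± 5.0 to 12.8 ± 0.42 CPM (SD, n = 4), 23.1-fold lower. Cth, an enzyme of cysteine synthesis, was 16.7-fold lower, and the stress regulators Ddit3 and Trib3 were 20.2-fold and 16.3-fold lower. Gsta1, a glutathione transferase, was 30.3-fold lower, though it belongs to a family of near-identical genes whose reads can be split. The carbonic anhydrase genes Car1 and Car6 were 20.7-fold and 20.5-fold lower, and Angptl6 was 19.9-fold lower. By smallest adjusted p, the leading increases were Thbs1, a matrix glycoprotein (34.2-fold, adjusted p = 3.06e-29), Fn1, Col6a3, Scd2 and Col1a1. The leading decreases were Lonp1, a mitochondrial protease (7.52-fold, adjusted p = 4.65e-28), Aldh1l2, Mthfd2, the autophagy receptor gene Sqstm1 (5.59-fold) and Trib3. These adjusted p-values are from edgeR.

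A set of 54 gene lists was tested with camera, and 29 were called at an adjusted p under 0.05. Of these, 21 were higher and 8 lower, and 10 were called also with an estimated correlation between genes. Adjusted over the list alone, the count of called members equalled the count over all genes in each of the 54 lists. Because low-expressed genes rose as a whole, each list median was also set against random lists of the same mean expression. The random lists were drawn gene by gene, so their range is too narrow for lists whose genes move together. Of the 21 lists called higher, 17 lay above the central 95% of the random lists, called the matched range. Of the 8 called lower, 6 lay below the matched range. Among lists not called, the unfolded protein response (percentile 100), fetal-like and YAP targets (99.9), tuft cell markers (99.8) and stem cell markers (99.4) also lay above it. A place outside the matched range does not replace the test with an estimated correlation. Mitochondrially encoded mRNAs lay at percentile 99.9, yet their estimated correlation was 0.686 and their camera adjusted p with it 0.408.

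**Figure D2:**
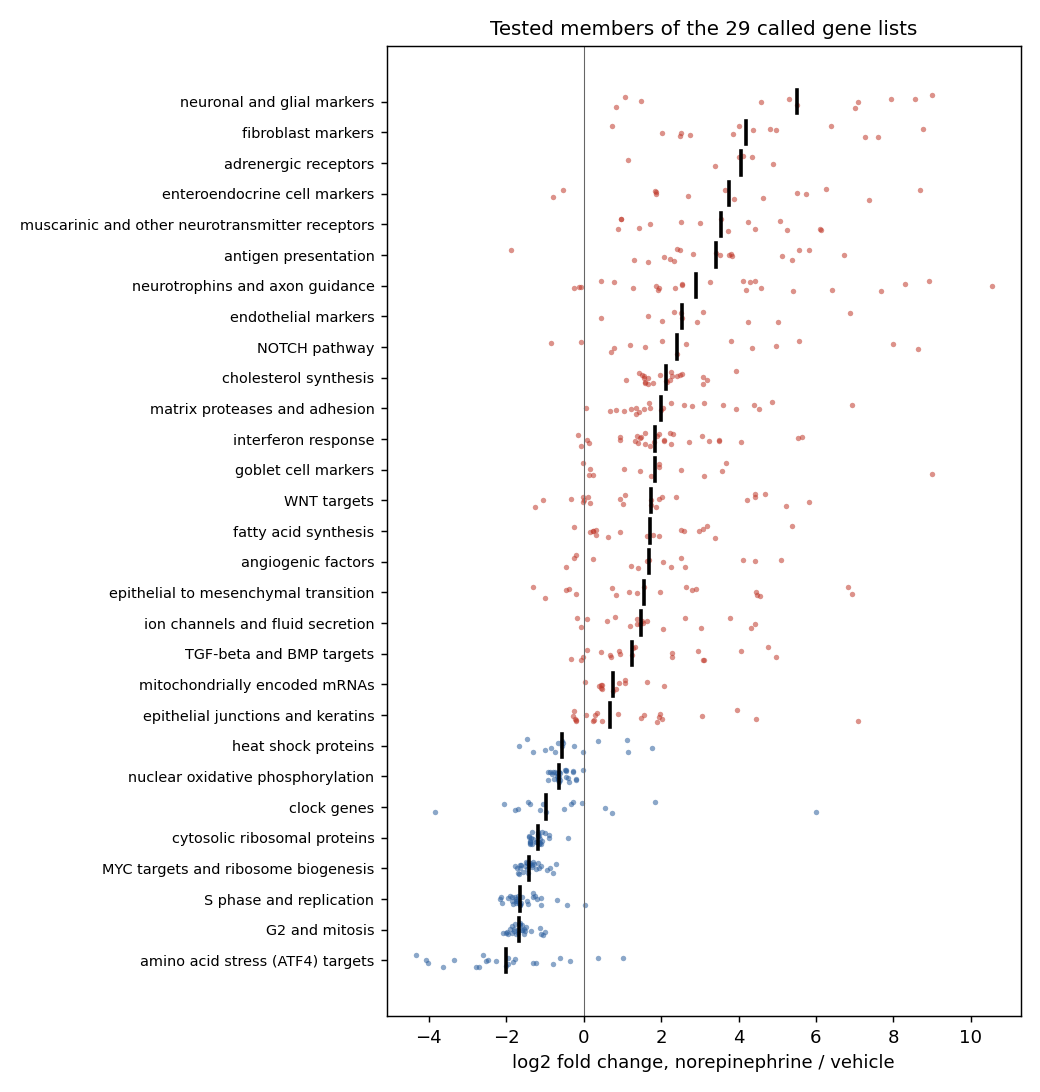
Log2 fold changes (norepinephrine over vehicle, horizontal axis) of the tested members of the 29 called lists, 1 row per list. Points are genes, black bars are list medians, red rows were called higher and blue rows lower; medians run from -2.00 for the amino acid stress list to 5.51 for the neuronal and glial list.

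Cell cycle genes fell as a body. All 28 tested genes of G2 and mitosis were lower (median log2 fold change -1.66, camera adjusted p = 2.49e-09, adjusted p = 0.0456 with an estimated correlation). Top2a, the replicative topoisomerase, fell from 925 ± 12 to 246 ± 3.5 CPM, and Kif20a, Ccna2 and Tpx2 were 3.96-fold, 3.35-fold and 3.49-fold lower. Mki67, the proliferation marker, fell from 611 ± 5.0 to 287 ± 2.75 CPM (SD, n = 4). Of 30 genes of S phase and replication, 29 were lower and Ccne1 was not called (median -1.66, adjusted p = 4.23e-09, adjusted p = 0.0351 with an estimated correlation). The helicase subunit genes Mcm2, Mcm5 and Mcm7 were 3.16-fold, 4.51-fold and 3.22-fold lower, and Rrm1, of nucleotide synthesis, 3.59-fold.

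Growth and translation genes fell with them. All 28 MYC target and ribosome biogenesis genes were lower (median -1.42, adjusted p = 3.41e-09), but the adjusted p was 0.0577 with an estimated correlation. The nucleolar genes Ncl, Npm1 and Nop56 were 3.14-fold, 3.22-fold and 3.43-fold lower, and Myc itself fell from 363 ± 5.0 to 152 ± 2.0 CPM. All 28 genes for cytosolic ribosomal proteins and translation factors were lower (median -1.19, adjusted p = 4.23e-09, adjusted p = 0.07 with an estimated correlation). Rps3, Rps24, Rpl4 and Rpl18 were 2.56-fold to 2.68-fold lower, and their many pseudogenes make single values uncertain. Nuclear genes of oxidative phosphorylation were lower in 27 of 28 cases, Ndufa4 not being called, with smaller changes (median -0.63, adjusted p = 3.22e-06, adjusted p = 0.07 with an estimated correlation). That median lay within the range of matched random lists, at percentile 5.83. Atp5b and Ndufv1 were 1.54-fold and 1.90-fold lower, while Sdhc and Uqcrfs1 turned under scaling by totals.

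The amino acid stress list, genes driven by the transcription factor ATF4, showed the lowest median of the 29 (-2.00, adjusted p = 1.09e-06, adjusted p = 0.0351 with an estimated correlation). Of its 23 genes, 21 were lower, and Fgf21 and Slc7a1 were higher. Atf4 fell from 949 ± 7.9 to 172 ± 2.5 CPM (SD, n = 4), and Mthfd2, a mitochondrial folate enzyme, was 6.86-fold lower. Heat shock genes were lower in 11 of 16 cases, of which Hspa4l turned under scaling by totals, and higher in 4, namely Hspa1a, Hspa1b, Hspb1 and Bag3 (median -0.56, adjusted p = 0.0494, adjusted p = 0.243 with an estimated correlation). The mitochondrial chaperone genes Hspd1 and Hspe1 were 3.19-fold and 2.76-fold lower. This call is borderline: its adjusted p was 0.0899 with a stricter count filter and 0.112 without mitochondrial and the 20 most abundant genes, and its median lay within the matched range, at percentile 27.9. Clock genes were lower in 12 of 17 cases and higher in 4, namely Per3, Hlf, Bhlhe40 and Bhlhe41 (median -0.97, adjusted p = 0.0437, adjusted p = 0.136 with an estimated correlation), among them Ciart (14.4-fold lower) and Arntl (2.62-fold lower).

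Lipid synthesis genes rose. All 23 cholesterol synthesis genes were past 2-fold higher (median 2.14, adjusted p = 4.34e-08, adjusted p = 0.0351 with an estimated correlation). Ldlr, the LDL receptor, rose from 48.2 ± 0.23 to 409 ± 4.5 CPM (SD, n = 4), Pcsk9, which degrades that receptor, 15.4-fold, Cyp51 8.41-fold and Hmgcs1 3.89-fold. Of 18 fatty acid synthesis genes, 17 were higher (median 1.72, adjusted p = 6.08e-05, adjusted p = 0.0351 with an estimated correlation). The other, Gpam, was lower by a small change that turned under scaling by totals. Scd2, a stearoyl-CoA desaturase, rose from 403 ± 4.5 to 3429 ± 9.9 CPM, its paralog Scd1, with which it can share reads, 7.95-fold, Fads2 10.4-fold and Acsl3 5.99-fold.

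Single epithelial adhesion genes rose. Cdh1, which encodes E-cadherin, rose from 16.1 ± 0.66 to 252 ± 4.4 CPM (SD, n = 4), and Epcam from 46.8 ± 1.3 to 387 ± 1.2 CPM. Of 22 junction and keratin genes, 16 were higher and 5 lower (median 0.67, adjusted p = 0.0201, adjusted p = 0.0784 with an estimated correlation), and the adjusted p was 0.068 after a correction for GC content. The lower ones were Tjp1, Krt8, Krt18, Krt19 and Ctnnd1, of which the last 3 turned under scaling by totals, under which 19 of the 22 were called higher. The desmosomal genes Dsg2 and Dsc2 were 3.86-fold and 3.95-fold higher, and Krt20, a marker of differentiated surface cells, 21.9-fold. All 23 genes of matrix proteases and adhesion were higher (median 1.99, adjusted p = 2.43e-06, adjusted p = 0.0454 with an estimated correlation). Lamb3, a laminin chain, rose 21-fold, Adam8 29.1-fold, the laminin receptor gene Itga6 4.81-fold and Itgb4 3.97-fold.

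The list of genes linked to the epithelial to mesenchymal transition went in both directions, with 14 of 19 higher and 5 lower, and 1 of the 5, Zeb2, turned under scaling by totals (median 1.56, adjusted p = 0.0437, adjusted p = 0.113 with an estimated correlation). Its call ended under scaling by totals, at an adjusted p of 0.0583, and by upper quartile, at 0.0626. Fn1, which encodes fibronectin, rose from 111 ± 2.8 to 2440 ± 14 CPM, Sparc 113-fold and Itgb1 6.97-fold. Vim, the mesenchymal intermediate filament gene, fell from 3074 ± 9.9 to 1239 ± 6.4 CPM (SD, n = 4). The other 4 that fell were Snai2, Zeb1, Zeb2 and Twist1, transcription factors of this transition.

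Markers of other cell types were tested as lists. A marker silent in vehicle passed the filter only if it was expressed with norepinephrine, so a rise of such tested markers was set in advance. Tested were 14 of 17 fibroblast, 11 of 15 neuronal and glial, 11 of 12 endothelial and 8 of 20 leukocyte markers. All 14 tested fibroblast markers rose (median 4.19, adjusted p = 9.32e-05, adjusted p = 0.0351 with an estimated correlation), among them Col1a1 from 0.358 ± 0.033 to 158 ± 0.48 CPM, Col6a3 31.2-fold, Col6a1 20.7-fold and Col5a1 28.0-fold. Col1a2, the usual partner chain of Col1a1, reached 0.517 CPM. All 11 tested neuronal and glial markers rose (median 5.51, or 5.21 with genes at 0 in vehicle set to their bound; adjusted p = 0.000767, adjusted p = 0.0456 with an estimated correlation). Uchl1 rose from 7.24 ± 0.38 to 173 ± 2.9 CPM, Elavl3 129-fold, Syp 39.4-fold and Stmn2 379-fold. All 11 endothelial markers were higher (median 2.55, adjusted p = 0.00791, adjusted p = 0.0784 with an estimated correlation), within the matched range at percentile 84.8. Egfl7 rose 8.54-fold and Kdr 19-fold. Cdh5 had 3 vehicle counts, a ratio of 135 and a counting interval of 46.0 to 658. Of these counts, 2 were in vehicle replicate 2, and the fitted log2 fold change of 6.87 was 7.80 without it. Leukocyte markers were not called (6 of 8 higher, 1, S100a9, lower, adjusted p = 0.165). S100a8 and Ptprc were 11.9-fold and 6.20-fold higher, the latter at 1.63 CPM.

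Most tested genes of the neurotrophin and axon guidance, neurotransmitter receptor and ion channel lists rose. Here too, a gene silent in vehicle was tested only if it was expressed with norepinephrine. A rise of such genes was set in advance. Of 24 tested neurotrophin and axon guidance genes, 20 were higher and 1, Efna1, lower by a change that turned under scaling by totals (median 2.90, adjusted p = 6.08e-05, adjusted p = 0.0351 with an estimated correlation). Ngf, which encodes nerve growth factor, rose 18.4-fold from 0.0989 ± 0.013 to 1.88 ± 0.34 CPM (SD, n = 4). Its receptor gene Ngfr rose 314-fold to 43.8 ± 0.54 CPM, the sorting receptor gene Sort1 85.5-fold and Nrp2 3.82-fold. Of 22 listed neurotransmitter receptor and cholinergic genes, 15 passed the filter, and all 15 were higher (median 3.54, adjusted p = 0.000399, adjusted p = 0.0454 with an estimated correlation). Among them were the muscarinic receptor gene Chrm4 (70.0-fold), Ache, which breaks down acetylcholine (69.3-fold), P2rx4 (2.71-fold) and Chrnb1 (1.96-fold). Of 18 ion channel and fluid secretion genes, 16 were higher and Slc26a3 and Aqp8 were not called (median 1.48, adjusted p = 0.000399, adjusted p = 0.113 with an estimated correlation). The chloride channel gene Ano1 rose 4.16-fold, the sodium pump genes Atp1a1 and Atp1b1 2.62-fold and 20.1-fold, and Slc12a2 2.60-fold.

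The receptors for norepinephrine were expressed at low levels. Receptor genes silent in vehicle passed the filter only if expressed with norepinephrine, which favours higher counts. All 6 tested adrenergic receptor genes were higher (median 4.06, adjusted p = 0.0437, adjusted p = 0.126 with an estimated correlation), a call that ended at an adjusted p of 0.0802 under scaling by totals and of 0.0557 to 0.0703 under upper quartile scaling and length or GC correction. Its median lay within the matched range, at percentile 97.1. Adrb2, the beta-2 receptor, had the highest level and went from 3.72 ± 0.24 to 8.20 ± 0.26 CPM (SD, n = 4). Adra1b reached 4.09 ± 0.26 CPM and Adra2a 3.34 ± 0.21 CPM, 10.4-fold and 20.4-fold higher. Adra2b, Adra1d and Adrb3 rose 16.2-fold, 29.6-fold and 17.2-fold and stayed under 2 CPM. Adrb1 had at most 8 counts in any library, Adra1a at most 5 and Adra2c at most 4, too few to be tested.

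Lists for signalling below these receptors were not called, nor were those for EGF family genes and for catecholamine uptake and breakdown. Only 48 h was sampled, so an earlier response that had ended by then could not be seen. Among 23 cAMP and CREB targets, 16 were higher and 6 lower (median 0.58, adjusted p = 0.129), with Ptgs2 2.41-fold higher and Areg, an EGF receptor ligand, 3.37-fold lower. Receptor desensitisation genes were higher in 10 of 15 cases and lower in 4, namely Grk2, Grk6, Arrb2 and Rgs19, the last turning under scaling by totals, which gave 11 and 2 (adjusted p = 0.173), with the arrestin gene Arrb1 2.67-fold and Rgs12 1.90-fold higher. Immediate early genes were higher in 8 and lower in 14 of 22 cases, or 10 and 10 under scaling by totals (adjusted p = 0.251), with Ccn1 5.80-fold higher. MAPK feedback genes were higher in 8 and lower in 11 of 19, or 11 and 7 under scaling by totals (adjusted p = 0.677; median -0.08, mean 0.24), with Epha2 2.37-fold higher and Fosl1 3-fold lower. EGF family genes were higher in 6 and lower in 3 of 11, namely Areg, Ereg and Btc, or 8 and 2 under scaling by totals (adjusted p = 0.275), with Egfr 7.83-fold higher. Catecholamine uptake and breakdown genes were higher in 4 of 8, namely Slc22a3, Slc18a1, Akr1b3 and Ddc, and lower in 3 (adjusted p = 0.767, tested direction lower, median 0.06). Adh5 was 2.42-fold and Aldh2 1.76-fold lower, and Maoa was lower too.

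WNT targets were mostly higher, with 17 of 23 up and 3 down (median 1.73, adjusted p = 0.00507, adjusted p = 0.0577 with an estimated correlation). Ephb2 rose 21.7-fold, Cd44 3.67-fold and Tnfrsf19 3.33-fold. Lgr5, the crypt stem cell receptor, rose from 7.41 ± 0.25 to 29.9 ± 0.84 CPM (SD, n = 4), while Myc, Ascl2 and Bambi fell. Axin2 stood at 227 and 223 CPM and was not called (adjusted p = 0.352). NOTCH pathway genes were higher in 13 of 15 cases and lower in 1, Nrarp (median 2.40, adjusted p = 0.00322, adjusted p = 0.0577 with an estimated correlation). Notch1 rose 20.4-fold, Notch2 2.99-fold, Notch3 401-fold and Notch4 47-fold. TGF-beta and BMP targets were higher in 17 of 20 cases and lower in 2, Bambi and Ski, the latter turning under scaling by totals, under which 19 of the 20 were called higher (median 1.26, adjusted p = 0.00046, adjusted p = 0.0948 with an estimated correlation). Ccn2 rose 7.72-fold to 517 ± 4.3 CPM, Serpine1 16.7-fold and Ltbp1 27.4-fold. Angiogenic factors were higher in 12 of 15 cases and lower in 3 (median 1.70, adjusted p = 0.0246, adjusted p = 0.123 with an estimated correlation), with Fgf2 4.17-fold and Pdgfb 5.74-fold higher. Vegfa, Vegfb and Pdgfc were the lower ones, and the last 2 turned under scaling by totals, which left 12 higher and 1 lower.

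Markers of intestinal cell types went in several directions. Those silent in vehicle passed the filter only if expressed with norepinephrine, which favours higher counts. Of 23 enteroendocrine markers, 14 passed the filter, with 12 higher and 2, Chgb and Isl1, lower (median 3.76, adjusted p = 0.0201, adjusted p = 0.0844 with an estimated correlation). The call ended at an adjusted p of 0.051 under scaling by totals and 0.0846 with a stricter filter. Cpe rose 6.45-fold, the neurotensin gene Nts 53.3-fold and Chga 14.7-fold to 2.60 ± 0.31 CPM. Goblet markers were higher in 10 of 14 cases, with Tff3, Clca1, Zg16 and Spink4 not called (median 1.85, adjusted p = 0.0239, adjusted p = 0.243 with an estimated correlation; 0.051 under scaling by totals), within the matched range at percentile 85.4. Galnt12 rose 8.58-fold. Creb3l1 reached 26.7 ± 0.80 CPM from 8 vehicle counts, 5 of them in vehicle replicate 2, so its fold rests on that library (log2 fold change 8.99, and 9.88 without it), and the mucin gene Muc2 went from 0.535 ± 0.20 to 1.49 ± 0.17 CPM. Colonocyte and enterocyte markers were not called, with 11 of 23 higher and 5, namely Car1, Car2, Fabp1, Apoa1 and Sis, lower (adjusted p = 0.452; median -0.01, mean 0.56). Cdhr2 was 15.8-fold and Cdhr5 3.48-fold higher. Stem cell markers (10 of 15 higher, 4 lower, adjusted p = 0.0636), tuft cell markers (8 of 10 higher, 2 lower, adjusted p = 0.089) and Paneth and deep crypt markers (4 of 9 higher, 1 lower, adjusted p = 0.566) were not called. Under other filters the stem cell list was called higher, at 0.0368 without a filter and 0.0174 with a stricter one, and so was the tuft cell list without a filter, at 0.0273. The lower ones were Ascl2, Olfm4, Cdca7 and Cdk6 among stem cell markers, Avil and Sh2d6 among tuft cell markers and Lyz1 among Paneth markers, where Mmp7, Pla2g2a, Kit and Nos2 were higher. Smoc2 rose 21.6-fold, Prom1 6.26-fold and Dclk1 13.1-fold, Avil was 3.63-fold lower, and Kit and Nos2 stayed under 1 CPM (fitted log2 fold change of Kit 4.46, and 5.06 without vehicle replicate 4). Fetal-like and YAP targets were higher in 15 of 23 cases and lower in 8, or 17 and 4 under scaling by totals (adjusted p = 0.107), with Spp1 5.32-fold higher, and the list was called higher at 0.0202 after a correction for transcript length.

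Immune recognition genes were higher. Of 19 antigen presentation genes, 18 rose and Psmb10 fell (median 3.42, adjusted p = 0.000221, adjusted p = 0.07 with an estimated correlation). The MHC class I genes H2-K1, H2-D1 and H2-T23 rose 4.67-fold, 2.46-fold and 5.28-fold, with reads that close relatives can share, and Tapbp, which loads peptides, 5.64-fold. Of 30 interferon response genes, 27 rose and 1, Stat1, fell by a change that turned under scaling by totals (median 1.85, adjusted p = 0.00037, adjusted p = 0.07 with an estimated correlation), within the matched range at percentile 94.2. Parp14, Gbp2, Ddx58 and Stat2 rose 11.3-fold, 6.60-fold, 3.73-fold and 2.74-fold. NF-kappaB targets were not called (14 of 25 higher, 10 lower, adjusted p = 0.775), with Cxcl16 2.16-fold higher and Tnfaip2 4.77-fold lower.

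Mitochondrially encoded mRNAs were higher in 12 of 13 cases, mt-Nd3 not being called (median 0.75, adjusted p = 0.00412), but the adjusted p was 0.408 with an estimated correlation. They made up 2.81% ± 0.10 of counts in vehicle and 5.50% ± 0.16 with norepinephrine (SD, n = 4). mt-Nd5 rose 3.12-fold, mt-Nd4 2.09-fold and mt-Co1 1.68-fold.

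The remaining lists were not called. Members higher and lower numbered 7 and 16 of 24 for oxidative stress (NRF2) targets (adjusted p = 0.0502), 13 and 6 of 20 for the unfolded protein response (0.0805), 6 and 13 of 20 for glycolysis (0.0974), and 7 and 12 of 20 for hypoxia targets (0.392; median -0.33, mean 0.15). They numbered 9 and 11 of 22 for apoptosis regulators (0.566; median -0.07, mean 0.16), 5 and 3 of 9 for metallothioneins and zinc transport (0.569), 11 and 9 of 21 for fatty acid oxidation (0.603), and 6 and 8 of 15 for lipolysis and glycogen (0.603; median -0.21, mean 0.49). They numbered 4 and 6 of 12 for glucocorticoid response genes (0.677; median -0.04, mean 0.09), 10 and 8 of 20 for p53 targets (0.919; median 0.06, mean -0.06), 7 and 7 of 15 for iron handling (0.928, tested direction lower, median 0.04), and 6 and 5 of 15 for AhR targets (0.948; median -0.11, mean 0.39). The oxidative stress list was at the threshold: its adjusted p ran from 0.0373 to 0.048 without vehicle replicate 1, 2 or 3 or norepinephrine replicate 1, 2 or 3, and it was called lower under other scalings too, at 0.0446 with library totals. The unfolded protein response list was called higher with the stricter filter (0.0434), and the glycolysis list lower without a filter (0.0273). Scaling by totals moved the numbers higher and lower to 9 and 10 for hypoxia targets, 13 and 6 for apoptosis regulators, 7 and 2 for metallothioneins and zinc transport, 15 and 5 for fatty acid oxidation, 6 and 4 for lipolysis, and 8 and 2 for glucocorticoid response genes. The median turned positive under scaling by totals for apoptosis regulators, lipolysis, glucocorticoid response genes and AhR targets, and for the MAPK and colonocyte lists above. Metallothionein and zinc genes that rose were Mt3, Slc30a1, Slc30a5, Slc39a4 and Slc39a10, and those that fell were Mt1, Slc30a4 and Mt2, the last turning under scaling by totals. Dusp1, Pdk4, Cdkn1a and Angptl4 were the higher glucocorticoid response genes, and Cyp1a1, Nqo1, Aldh3a1, Cyp3a13 and Ces2a the lower AhR targets. Among single members, the haem oxygenase gene Hmox1 fell 5.53-fold, Gclm 3.14-fold, Nqo1 4.30-fold, Eno1 2.18-fold, Ldha 1.81-fold, Ndrg1 4.20-fold, Herpud1 4.33-fold, Pparg 5.05-fold, Pck2 4.93-fold, Sesn2 6.08-fold, Casp3 2.34-fold and Tsc22d3 3.16-fold. The list of small nucleolar RNA hosts and histone genes had 4 members with enough counts and was not tested. Of these, Hist2h2be had a log2 fold change of -0.84, Hist1h2bc of 0.45 and Hist1h1c of 0.16 (adjusted p = 0.00793), and Hist1h4i was not called. Car9 rose 11.7-fold, Ucp2 7.46-fold, Cyp1b1 5.97-fold, Slc39a10 4.76-fold, Slc39a14 3.04-fold and Tnfrsf10b 3.92-fold.

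Transcripts of the engineered genes were present in both groups, which does not test the alleles because reads can come from parts left in place. Apc stood at 198 ± 1.6 and 235 ± 2.1 CPM, Kras at 166 ± 4.0 and 130 ± 1.1 CPM, and Trp53 at 27.1 ± 0.80 and 16.4 ± 0.84 CPM in vehicle and norepinephrine (SD, n = 4). The Apc direction turned, to a log2 fold change of -0.19, after a correction for transcript length.

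**Figure D3:**
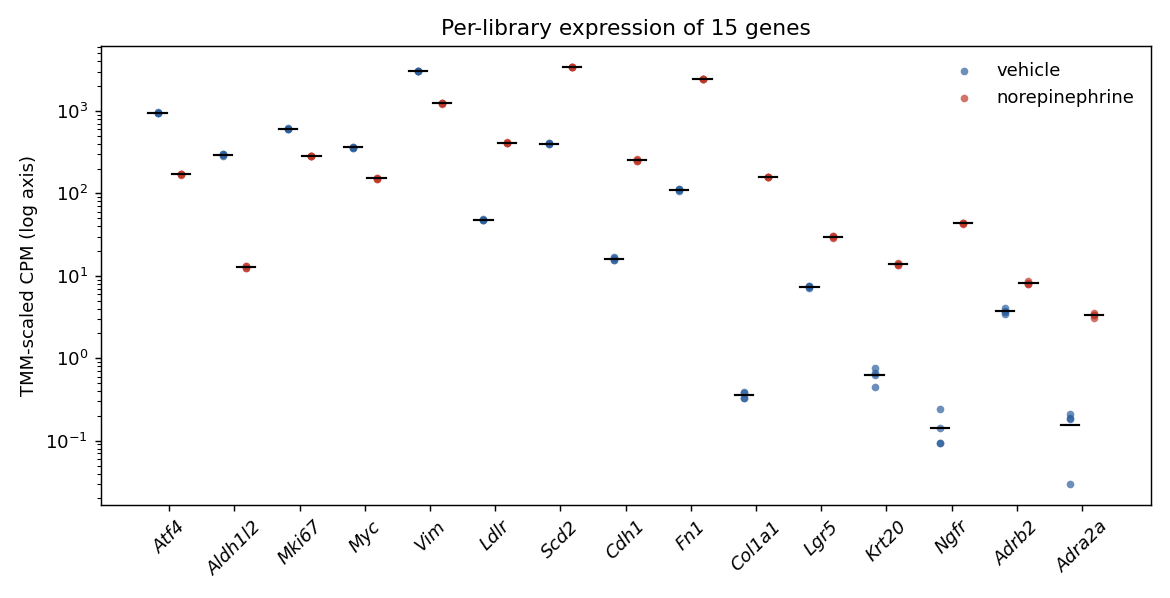
TMM-scaled CPM (vertical log axis) of 15 genes in each library. Blue points are the 4 vehicle and red points the 4 norepinephrine libraries, and bars are group means; the groups separate for each gene, for example Cdh1 at 16.1 against 252 CPM and Atf4 at 949 against 172 CPM.

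Genome positions, in GRCm38, of genes central to these comparisons are as follows. Atf4 lies on chromosome 15 from 80255184 to 80257541, Cdh1 on chromosome 8 from 106603351 to 106670246 and Ldlr on chromosome 9 from 21723483 to 21749919. Col1a1 lies on chromosome 11 from 94936224 to 94953042, Thbs1 on chromosome 2 from 118111876 to 118127133 and Adrb2 on chromosome 18 from 62177816 to 62179959. All are annotated as protein-coding genes.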

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

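The tests chosen only after results were seen were the comparison of chromosome medians, the 8 further neuronal transcripts, the setting of the falling lists against matched lists, the comparison of olfactory receptor genes with other genes and the removal of length and GC trends as a setting.

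Within each group of 4 libraries, the library farthest from its nearest neighbour was compared with the group's range. Of 384 groups of values tested, 21 held a library set apart, or 5.47%, and chance gives about 5%. Vehicle replicate 4 had a total of 35997701 counts, or 36 M, against 45917236 to 47340204 in the other vehicle libraries. It also had 18815 genes above 0, or 18800 after rounding, against 19316 to 19403, and stood at -32.3 on the second principal component against 7.13 to 13.9.

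The rest were single genes in CPM. In vehicle libraries, Ache was 0.212 in replicate 2 (others 0.116 to 0.12), Adgrb2 0.0695 in replicate 3 (others 0) and Adra2a 0.03 in replicate 4 (others 0.185 to 0.212). Atf4 was 960 in vehicle replicate 1 (others 943 to 945), Dsg2 32.1 in replicate 1 (others 29.8 to 30), Ngf 0.118 in replicate 1 (others 0.0902 to 0.0943), Lamb3 9.85 in replicate 2 (others 11.2 to 11.3) and Rps24 1120 in replicate 3 (others 1080 to 1090). In norepinephrine libraries, Cdh5 was 2.32 in replicate 4 (others 2.57 to 2.6), Egfr 77.6 in replicate 4 (others 75.6 to 75.9) and Fosl1 51.8 in replicate 4 (others 54.1 to 54.4). Col6a1 was 161 in norepinephrine replicate 1 (others 158 to 159), Spp1 1120 in replicate 1 (others 1130 to 1140), Ddx58 34 in replicate 2 (others 32.9 to 33.1) and Lamb3 222 in replicate 2 (others 229 to 230). Hspe1 was 73.7 in norepinephrine replicate 3 (others 76.8 to 77.1), Pck2 42.4 in replicate 3 (others 41 to 41.2) and Thbs1 541 in replicate 3 (others 549 to 551).

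The first pattern weighed is the extent of the change. Of 35 splits of the 8 libraries into groups of 4, 1 called as many genes, the real one with 14342. The highest other called 0 with edgeR (90 at an unadjusted p under 0.05). Every other split mixes the groups, so the real difference widens its spread and low counts were bound to follow. The splits therefore cannot exclude a chance difference between the cultures behind the groups. Of the genes past 2-fold, 89.4% stayed so after each library's trend with transcript length was removed and 92% after that with GC content, which argues against either trend as the whole source. Autosome medians lay within 0.11 log2 of their common median, which argues against whole-chromosome differences between the lines behind the groups. A difference in culture, such as growth state, handling or an unlike line with focal differences, was not tested, and an effect of norepinephrine may be behind the pattern only as a hypothesis.

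The second pattern is the 578 genes near 0 in vehicle and on with norepinephrine. RNA of fibroblasts would bring its abundant transcripts together. The panel was split: Sparc at 137 and Col3a1 at 53.9 CPM lay above 10% of the Col1a1 level of 158 CPM. The planned bound was reached, as 3 of 5 lay below that limit, with Col1a2 at 0.517, Dcn at 0.358 and Lum at 0.0312 CPM. These 3 argue against fibroblast RNA as the source. Of olfactory receptor genes, 2.63% reached 1 CPM (37 of 1405, and 25 in vehicle), and 0 of 1143 near 0 in vehicle came on (95% exact upper limit 0.322%) against 575 of 6540 other protein-coding genes (8.79%), which argues against background transcripts or DNA. RNA of neurons cannot be told apart: 1 of 5 planned transcripts, and 3 of 8 further ones picked with levels in view (Stmn3, Rtn1 and Nefm), lay below 10% of the Stmn2 level of 17.5 CPM, so the planned bound of 2 was not reached. Activation of silent genes in the organoid cells may be behind the pattern, as a hypothesis that stays open beside it.

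The third pattern is the fall of the S phase, mitosis, MYC, ribosomal and ATF4 lists. One factor per library moves all genes alike, so it cannot lower a list relative to genes of like expression. The 5 medians lay at percentile 0.03 or lower among random lists of such genes. The 5 lists were taken because camera had called them lower against the other genes. Their low place was therefore to be expected and is not independent support. How far they fell in absolute terms stays open: under the scalings tried the highest median was -0.94, but these shift genes by at most 0.25 and could not have undone the fall. All 5 lists stayed called lower by camera with its preset correlation after removal of the length trend, and all 5 after removal of the GC trend, though with an estimated correlation the MYC (0.0577) and ribosomal (0.07) lists were not called even before these corrections. Slower growth under norepinephrine may be behind it as a hypothesis, and a difference in culture density or medium between groups was not tested.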

How the results depend on the processing

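The tests against a fold of 2, the length, GC and thinning settings, the upper quartile and composition settings for lists and the matched lists were chosen after results were seen. The counts of genes called, higher and lower stayed within 1.5 times of 14342, 7483 and 6859 under every alternative except the test against a fold of 2, which called 6091 genes, 4496 higher and 1595 lower, as its stricter question implies. The near-even split depended on the scaling: library totals gave 8699 higher and 5601 lower, and upper quartile scaling gave 8420 and 5896. Genes lower past 2-fold fell from 1911 to 1008 with library totals and 1173 with upper quartile scaling, since these raise every fold change. Of 6815 genes past 2-fold either way, 86.7% and 89.2% remained past it. The DESeq2 Wald test called 15284 genes, limma-voom 14330, no filter 15936 and the stricter filter 12634.

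Leaving out 1 library at a time gave 14292 to 14554 genes called, 7437 to 7630 higher, 6855 to 6924 lower, and 29 to 30 lists.

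Camera with an estimated correlation called 10 lists, 7 higher and 3 lower. Fry, which does not compare a list with other genes, called 54, 35 higher and 19 lower, and reversed the direction of 3 uncalled lists, MAPK feedback targets (adjusted p = 0.00193), iron handling (1.84e-06) and NF-kappaB targets (0.00142). Under other settings calls ended for the adrenergic receptor list (0.0557 to 0.0802), the heat shock list (0.0522 to 0.112), the enteroendocrine list (0.051 and 0.0846), the goblet list (0.051), the transition list (0.0583 and 0.0626) and the junction list (0.068), and the cause was not tested. The oxidative stress list was gained in 6 of 8 fits without 1 library (0.0373 to 0.048), with library totals (0.0446), upper quartile (0.0486) and DESeq2 size factors (0.0491), on ranks (0.0374) and without a filter (0.00875). Other filters, ranks or the length setting also gained the stem cell (0.0174 to 0.0368), tuft cell (0.0273), glycolysis (0.0273), unfolded protein (0.018 to 0.0434) and fetal-like lists (0.0202 to 0.0367).

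Of 190 tested named genes, Apc reversed, from a log2 fold change of 0.25 to -0.19 with the length trend removed, and was not called against a fold of 1.2. The cause was not tested. Against a fold of 2, 17 named genes were not called.

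Replicate numbers are shared between groups, but same-numbered libraries did not deviate together (correlations -0.12, -0.13, 0.18 and -0.23), so they were not treated as pairs. With the replicate number as a block, 14223 genes were called, 7417 higher and 6806 lower, and 28 lists, the heat shock list ending at 0.0522. The counts as deposited without rounding were not run, since all are whole. At this depth, genes under the filter, among them 3 adrenergic receptor genes, were not testable.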

Other observations

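All tests here were run on gene families chosen after the data were seen, from the names among the strongest changes, so their p-values describe these data only. For the same reason, a place outside the range of random lists was to be expected and is not independent support. Counts cover only family members that passed the filter.

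Each family's median was also set against random lists of the same mean expression. All 20 aminoacyl-tRNA synthetase genes were lower (median log2 fold change -1.80, camera adjusted p = 1.42e-08, adjusted p = 0.0158 with an estimated correlation), with Nars at 978 and 211 CPM, Rars at 592 and 118 CPM in vehicle and norepinephrine. Of 77 mitochondrial ribosomal protein genes, 76 were lower (median -0.94, adjusted p = 4.54e-13, adjusted p = 0.0043 with an estimated correlation), or 68 lower and 1 higher under scaling by totals. Both medians lay below the central 95% of the random lists, which ran from -0.86 to -0.10 (log2) for the synthetases and from -0.51 to -0.04 for the mitochondrial ribosomal proteins. Of 38 proteasome subunit genes, 35 were lower and 2, Psmb8 and Psmb9, higher (median -0.60, adjusted p = 1.47e-07, adjusted p = 0.0408 with an estimated correlation). That median lay within the range of the random lists, from -0.62 to -0.05, so the family did not stand apart from genes of like expression by this measure.

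Genes silent in vehicle passed the filter only through norepinephrine libraries, which favours higher counts in these families. All 38 tested collagen chain genes were higher (median 3.92, camera adjusted p = 9.15e-09), as were 57 of 58 tested potassium channel genes (median 3.30, adjusted p = 1.42e-08). So were all 16 tested WNT ligand genes (median 4.81, or 4.31 with genes at 0 in vehicle set to their bound, adjusted p = 2.59e-05). Of 40 tested protocadherin genes, whose clustered members share sequence, 39 were higher (median 4.61, or 4.53 with such genes at their bound, adjusted p = 8.8e-07). All 16 synaptotagmin genes (median 3.65, adjusted p = 0.000118), 16 of 19 voltage gated calcium channel genes (median 3.66, adjusted p = 0.000894) and 17 of 20 ephrin and ephrin receptor genes (median 1.94, adjusted p = 0.000123) were higher too. The medians of these 7 families lay above the central 95% of random lists of like expression, at percentile 99.6 for synaptotagmins and higher for the others. They are not separate from the marker lists: 6 collagen chain genes are also fibroblast markers, and RNA of neurons, which was not excluded (1 of 5 planned transcripts below its limit), would raise channel and synaptotagmin genes as well. Lower were the calcium channel genes Cacnb2 and Cacna1e, the potassium channel gene Kcnj14 and Efna1, whose direction turned under scaling by totals. Cacng2, Pcdhgc4, Efnb3 and Epha5 were not called. Wnt7b went from 49.0 to 193 CPM and Wnt4 from 2.08 to 38.2 CPM.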
